A study of Mus musculus with 6 samples.

How the data were processed

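The series measured messenger RNA, ribosome footprints and RNA bound by a tagged enzyme in E14 mouse embryonic stem cells. E14 is an established embryonic stem cell line, grown here on gelatin in serum medium with LIF, per the labels' protocols. Wild-type cells received a non-targeting siRNA pool (siCtrl) or an siRNA against PKM1 and PKM2 (siPKM) at 20 nM for 36 h and were passaged 16 h before harvest. From each culture condition there was 1 library of rRNA-depleted total RNA and 1 library of ribosome-protected fragments (RPF). Per the labels' protocols, cycloheximide was given at 100 µg/ml for 2 min, footprints were made with RNase A and RNase T1 and not with RNase I, and ribosomes were pelleted through a sucrose cushion. The other 2 libraries were FAST-iCLIP replicates from cells with FLAG-HA-tagged PKM2, crosslinked with UV light at 0.35 J per cm2. In iCLIP, reverse transcription tends to stop next to a crosslinked base, and stops were counted, background included. Groups were taken from the sample titles. Nothing in the labels says that the CLIP replicates came from separate cultures, so their SD may be technical.

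All 6 libraries were in a single table. It held raw counts of reads per transcript, deposited by the authors for the 5' UTR, the first 15 codons, the rest of the coding sequence (CDS), the last 5 codons and the 3' UTR, per the file headers. It also held raw counts of reverse transcription stops per mature transcript for each CLIP replicate, per the file headers. The authors also deposited log2 RPM, log2 translation efficiency (footprints over RNA) and log2 CLIP enrichment. From the values, the authors' log2 enrichment was the library-scaled stops (CPM) plus 1 over the RPM of the control RNA library, and their totals for RNA and RPF were larger than the sums over the table. Reads were processed with cutadapt and Bowtie2 against the mm9 build, per the submitters' processing notes. Their versions, the counting tool and the treatment of reads with several matches were not given in the sources used here. Ribosomal proteins, glycolytic enzymes and histones have near-identical copies or pseudogenes, so their single-gene values and list medians are uncertain. The handling of strand was not given in the sources used here either, so reads of overlapping antisense genes could not be told apart. 1 column with no sample of its own was not used.

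The table had 6535 rows, and every row exceeded 150 CDS reads in each of the 4 RNA and RPF libraries. A gene that dropped below that level in any library is therefore not analysed here. Where a symbol had several rows, the row with the highest mean RNA count was used, which dropped 3 rows and left 6532 genes. The planned floor, a mean of 64 CDS reads in RNA and in RPF, removed 0 genes. RefSeq identifiers of 6468 genes were matched to a gene table of assembly GRCm38.p6, which was used for current names only and gave a different current symbol for 637. No coordinates are given because that assembly differs from mm9.

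CDS reads, without the first 15 and last 5 codons, gave log2 ratios of siPKM over siCtrl after adding 0.5 reads and scaling by the library's sum. The ratios were centred on the median of all 6532 genes. The change in translation efficiency (TE) was the RPF log2 ratio minus the RNA log2 ratio, centred again. All ratios are thus relative to the median gene, and a change shared by all genes cannot be seen. Each siRNA group had 1 library of each kind, so no test of the conditions was possible, no p-value is given and no difference has a replicate check. Genes at least 1.5-fold apart were counted instead, beside the counts from 100 simulations in which reads alone varied. Intervals of ratios are 95% intervals from the read counts, and shares of reads have exact Clopper-Pearson intervals. They cover counting error only, and PCR reads without molecular identifiers are not independent molecules. CLIP over RNA was the log2 of the mean CPM of stops in both replicates over the CPM of control RNA reads on the whole transcript, with 0.5 counts added. A CLIP count of 0 allows up to 4.43 CPM in replicate 1 and 4.47 in replicate 2, taking 3 counts as the limit.

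Before the data were examined, 27 gene lists, the naming rule, the thresholds and most alternatives were fixed. The lists were 7 of the secretory pathway (ER chaperones, ER translocation and N-glycosylation, secreted and matrix proteins, plasma membrane receptors and adhesion proteins, lysosomal and Golgi proteins, solute carriers outside Slc25, numbered transmembrane proteins), mitochondrial Slc25 carriers, Zfp zinc finger proteins, cytosolic and mitochondrial ribosomal proteins, the nuclear-encoded respiratory chain, proteasome and chaperonin subunits, translation factors, glycolytic enzymes, ATF4, CHOP and unfolded protein targets, p53 targets, cholesterol synthesis and uptake, interferon response, cell cycle, replication-dependent histones, mitochondrially encoded genes and pluripotency genes. The last 4 were markers of primitive endoderm, trophoblast, primitive streak with mesoderm and neural cells, and fibroblasts. A list with at least 3 members in the table was described by its median and by that median's percentile among 10000 random lists of the same size, matched in 10 groups of mean RNA level (control RNA level for CLIP over RNA). 23 lists had that many members, and a median outside the central 95% of its random lists is called outside the random range. Such percentiles describe these libraries and are not tests of the knockdown. By chance 5% of lists would lie outside if their genes varied independently. Genes of the same list can vary together between cultures or libraries, so more lists may lie outside without an effect of the knockdown.

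Named genes were the 5 highest and 5 lowest in RNA and in RPF, the 10 highest and 10 lowest in TE, the 20 with the most CLIP stops, the 10 highest in CLIP over RNA among genes above the median stops (55 and 54) in the replicates, the 2 highest and 2 lowest members in TE of each list, Pkm, Pklr and the glycolytic enzymes. Of these genes, 1 is not reported here. Genes with the highest CLIP over RNA (the tenth of the genes, 653) were compared in TE with random sets in the same way.

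The alternatives were a smaller and a larger pseudocount, a 4-fold higher floor, scaling by the authors' totals, TMM, a 2-fold threshold, unmatched random lists, the mean of both RNA libraries as the reference for CLIP over RNA, other sizes of the CLIP-high set and leaving out each CLIP replicate. Added after seeing the data were random lists matched on a coding length index (CDS reads per read in the first 15 and last 5 codons), CLIP set against control footprints, siPKM RNA or the mean of both RNA libraries as the reference for choosing the CLIP-high set, 2 wider gene sets, and scaling of the list medians. Simulated data with 200 changed genes among 6532 were used to test the ratios. Passing the 1.5-fold line were 44.8%, 98.5% and 100% of the genes changed 1.5-, 2- and 3-fold in RNA, 47.8%, 100% and 100% in RPF, and 49.3%, 100% and 100% in TE. A gene changed by exactly the threshold passes about as often as not at any depth. Among unchanged genes 0% passed in RNA, 0% in RPF and 0.0316% in TE. These simulations held counting error only, so their rates do not cover differences between cultures or libraries. The log2 ratios of the data had an SD of 0.276 in RNA, 0.275 in RPF and 0.201 in TE. Counting error alone gave 0.0865, 0.0853 and 0.121. Of 200 simulated lists of 30 genes, 4.5% lay outside the random range with no shift and 100% with a shift of 0.2. Their genes were drawn at random, so these rates do not cover lists whose genes vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and edgeR 4.0.16 (TMM factors) were used.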

Results

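Ribosome footprints and messenger RNA were compared between embryonic stem cells with and without knockdown of pyruvate kinase M, and the RNAs crosslinked to tagged PKM2 were mapped in the same cell line. The table held 12122153 CDS reads for siCtrl RNA, 10357272 for siPKM RNA, 15193841 for siCtrl RPF and 12559907 for siPKM RPF. The median gene had 764, 689, 838 and 704 CDS reads in these libraries. Footprints lay in the CDS for 86.4% (siCtrl) and 86.8% (siPKM) of RPF reads and in the 3' UTR for 0.205% and 0.191%, whereas 28.7% and 29.2% of RNA reads lay in the 3' UTR. The CLIP replicates had 677701 and 670725 reverse transcription stops. Each siRNA group had 1 library of each kind, so the differences between siPKM and siCtrl below have no replicate check.

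The targeted gene, Pkm (Pkm2 in the table, NM_011099), encodes pyruvate kinase M, which makes pyruvate in the last step of glycolysis. It had the lowest ratio of all 6532 genes in RNA and in RPF. Its share of CDS reads was 0.481% (95% Clopper-Pearson interval 0.477 to 0.484) in siCtrl RNA and 0.151% (0.149 to 0.153) in siPKM RNA. Among footprints the share was 0.512% (0.509 to 0.516) in siCtrl and 0.162% (0.160 to 0.164) in siPKM. The log2 ratios were -1.71 in RNA and -1.68 in RPF, and that of TE was 0.03 (-0.00 to 0.07), so a TE difference of Pkm was not detectable. The row does not separate the splice forms PKM1 and PKM2. Pklr, the liver and red cell pyruvate kinase, was not among the genes used.

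The knockdown library's messages were compared with those of the control. Highest in siPKM RNA were Fam129a (Niban1), with a log2 ratio of 1.66 (1.48 to 1.86) from 313 and 876 reads, Mme, the membrane endopeptidase neprilysin, at 1.36 (1.16 to 1.57), and Ly75, an endocytic receptor, at 1.33 (1.24 to 1.41). Prex2, a guanine nucleotide exchange factor for Rac, followed at 1.29 and Grik3, a glutamate receptor subunit, at 1.25. After Pkm, the lowest were Psmb10, an immunoproteasome subunit, at -1.20 (-1.45 to -0.95) from 484 and 186 reads, Cdkn1c, a cyclin-dependent kinase inhibitor, at -1.14, Hsd17b14, a hydroxysteroid dehydrogenase, at -1.10, and Notum, a secreted inhibitor of Wnt proteins, at -1.09. At least 1.5-fold higher in siPKM RNA were 188 genes, and 81 were at least 1.5-fold lower. Simulations of counting error alone gave 0.03 and 0.03 on average.

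Footprints were compared in the same way, as a measure of the ribosomes on each message. The highest ratios were those of Mme at 1.83 (1.64 to 2.03), Fam129a at 1.70, the secreted protease Htra1 at 1.37, Plin2, a coat protein of lipid droplets, at 1.37, and Ly75 at 1.36. After Pkm, the lowest were Psmb10 at -1.32 (-1.59 to -1.05), Ina, a neuronal intermediate filament, at -1.24, the transcription factor Dmrt1 at -1.23 and the adenylate kinase Ak1 at -1.15. At least 1.5-fold higher were 174 genes and 100 were lower, against 0.02 and 0.03 from counting error. Of the genes higher in RNA, 102 were also at least 1.5-fold higher in RPF (5.01 for independent lists), and of those lower in RNA, 48 were also lower in RPF (1.24). Footprints depend on message level, so such an overlap would follow any RNA difference between the cultures and is no replicate check. Across genes, which are not independent replicates, RNA and RPF ratios had a Pearson correlation of 0.73 and a Spearman correlation of 0.67.

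**Figure D1:**
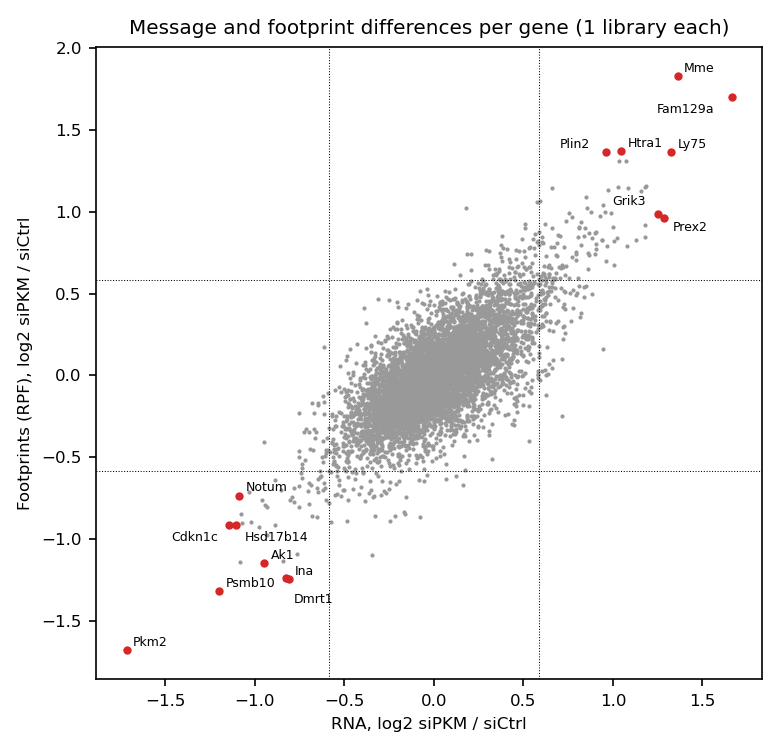
Each point is 1 of the 6532 genes, with the log2 ratio of siPKM over siCtrl in RNA on the horizontal axis and in footprints on the vertical axis; dotted lines mark 1.5-fold, and red points are the 5 highest and 5 lowest genes of each kind. Pkm2 lies lowest on both axes, at -1.71 and -1.68.

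Several groups of proteins made at the endoplasmic reticulum (ER) were higher in both kinds of siPKM library. Secreted and matrix proteins (32 genes) had a median log2 ratio of 0.34 in RNA and 0.44 in RPF, each above all 10000 matched random lists. In RNA 10 of them were at least 1.5-fold higher and 1 lower, and in RPF 11 higher and 1 lower. Among them were fibronectin (Fn1) at 0.90 in RNA and 0.74 in RPF, the basement membrane proteoglycan Hspg2 at 1.00 and 0.82, and the collagen Col4a2 at 0.51 and 0.92. Lysosomal and Golgi proteins (34) had medians of 0.29 and 0.37, again above all random lists, with the lysosomal membrane protein Lamp2 at 0.46 and 0.77 and the glucuronidase Gusb, which went the other way, at -0.36 and -0.72. Plasma membrane receptors and adhesion proteins (60) had medians of 0.21 (above all random lists) and 0.16 (percentile 99.99), with the ephrin receptor Ephb2 at 0.77 and 0.33. In that list 9 genes were at least 1.5-fold higher in RNA and 1 lower, and 3 higher in RPF and 0 lower. ER chaperones (31) had medians of 0.12 (above 99.5% of random lists) and 0.24 (above all), with Hspa5, the ER Hsp70, at 0.21 and 0.33 and the lectin chaperone Calr at 0.31 and 0.40. The ER translocation and N-glycosylation machinery (31) was inside the random range in RNA, at 0.04, and above 99.8% of random lists in RPF, at 0.13. Solute carriers outside Slc25 (63) were above 99.4% in RNA, at 0.11, and inside the range in RPF, at 0.06. Numbered transmembrane proteins (60) were inside both ranges, at 0.06 and 0.08.

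Histone messages were the lowest list. Replication-dependent histones (16 genes), which package newly made DNA, had medians of -0.46 in RNA and -0.45 in RPF, below all random lists, with 5 genes at least 1.5-fold lower in RNA, 6 in RPF and 0 higher in either. The histone Hist1h4f stood at -0.48 and -0.09. Cell cycle genes (23) had medians of -0.17 and -0.16, at percentiles 1.30 and 0.46, with the mitotic kinase Plk1 at -0.50 and -0.41 and the cyclin Ccnb1 at -0.31 and -0.16, whereas the proliferation marker Mki67 stood at 0.58 and -0.02. p53 targets (10) had medians of -0.34 (percentile 0.01) and -0.29 (0.10), with Zmat3, an RNA-binding protein, at -0.38 and -0.77 and the apoptosis effector Bax at -0.36 and -0.01. Proteasome and chaperonin subunits (44) were lower in RNA, at -0.19 (percentile 0.01), with 42 of the 44 below 0, and inside the range in RPF, at -0.07. Translation factors (52) had medians of -0.13 (percentile 1.17) and -0.06 (inside), and mitochondrial ribosomal proteins (74) of -0.12 (below all random lists, but inside those matched on coding length, at 3.58) and -0.09 (percentile 0.34).

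Glycolytic enzymes other than Pkm (13) did not move as a block. Both lactate dehydrogenase genes differed, in opposite directions, with Ldha at -0.74 (-0.80 to -0.68) in RNA and -0.60 in RPF, and Ldhb at 0.88 (0.79 to 0.96) and 1.00. Eno3 (-0.55 and -0.52), Tpi1 (-0.43 and -0.29), Pgam1 (-0.34 and -0.45) and Pfkl (-0.18 and -0.24) were lower in both, and Hk2 (0.23 and 0.36), Aldoa (0.10 and 0.24) and Gpi1 (0.10 and 0.15) higher in both. Hk1 stood at 0.09 in RNA and 0.46 in RPF, Pfkm at 0.05 and 0.29, Pfkp at -0.03 and 0.02 and Pgk1 at -0.16 and 0.03. The list medians of -0.03 in RNA (0.01 when scaled by the authors' totals) and 0.03 in RPF were inside the random range.

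Cholesterol genes (17) had a median of 0.11 in RNA, inside the range, and 0.20 in RPF (percentile 99.9), with the sterol oxidase Sc4mol (Msmo1) at 0.58 and 0.81, but with the floor 4 times higher the RPF median of 0.05 was inside the range. Cytosolic ribosomal proteins (75) were inside the range in RNA, at -0.08, and above all random lists in RPF, at 0.07, and the nuclear-encoded respiratory chain (82) stood at -0.06 (inside) and 0.04 (percentile 99.1, but 89.2 and inside the range among unmatched lists). The medians of 6 further lists were inside the range in RNA and RPF. These were pluripotency genes (25) at 0.07 and -0.04, ATF4, CHOP and unfolded protein targets (22) at -0.02 (0.02 with the authors' totals) and 0.06, interferon response genes (8) at -0.12 and 0.03, Slc25 carriers (17) at 0.02 and 0.00, Zfp zinc finger proteins (100) at 0.05 and 0.01, and trophoblast markers (3) at 0.37 and 0.32. Median and mean differed in sign in RNA for the ATF4 list (mean 0.02) and for Slc25 carriers (mean -0.01). Outside the random range were 11 of 23 lists in RNA and 12 in RPF.

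Few markers of other cell types were in the table. Of the trophoblast markers, the keratins Krt8 (0.59 in RNA and 0.87 in RPF) and Krt18 (0.37 and 0.32) were higher in the siPKM libraries, as were the secretory lists, and the transcription factor Tcfap2c (Tfap2c) was lower (-0.60 and -0.76). Vimentin (Vim), the fibroblast marker present, stood at 0.36 and 0.42, and the primitive endoderm marker Cubn at 0.07 and 0.01. The neural markers Nes (-0.54 and -0.72) and Pax6 (-0.15 and -0.15) were lower.

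The change in TE asked which messages carried more or fewer ribosomes per message after knockdown, relative to the median gene. A rise or fall of translation common to all genes was removed by the centring. Os9, an ER lectin that takes misfolded proteins to degradation, had the highest TE ratio at 0.84 (0.48 to 1.20), with RNA at 0.18 and RPF at 1.02. Psmc3ip, a meiotic recombination factor, followed at 0.80, the initiation factor Eif1a at 0.78, Ubl4 (Ubl4a) at 0.77, the lipid transfer protein Pitpnc1 at 0.71, the kinase Sgk3 at 0.70, Ssna1 at 0.65, the mitochondrial valyl-tRNA synthetase Vars2 at 0.62 and Hscb, a cochaperone of iron-sulfur cluster assembly, at 0.62. The lowest was the zinc finger protein Zfp932 at -0.97 (-1.34 to -0.59). It was followed by mt-Nd4, the mitochondrially encoded gene in the table, at -0.93 (-1.07 to -0.80), with RNA at 0.53 and RPF at -0.40, the mitochondrial carrier Ucp2 at -0.84, Rnf10 at -0.83, the RNA polymerase III factor Bdp1 at -0.79, the synaptic scaffold Dlgap3 at -0.79, the scaffold Iqgap1 at -0.76, the splicing kinase Clk1 at -0.75, Ankrd52 at -0.75 and the ankyrin Ank2 at -0.75. The row named mt-Nd4 was described in the table as chain 4L of the complex, so its identity is uncertain. At least 1.5-fold higher in TE were 12 genes and 54 were lower, against 1.08 and 1.28 on average from counting error alone. The most in any 1 simulation was 6 in either direction. In the data 0 genes reached 2-fold. In the authors' deposited table the log2 TE difference, which was not centred, gave 10 and 64.

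Several housekeeping complexes had higher TE in siPKM, which did not always go with more footprints. Against lists matched on RNA level, RPF medians were above the random range for cytosolic ribosomal proteins and the respiratory chain. They were inside it for proteasome and chaperonin subunits, translation factors and glycolytic enzymes, and below it for mitochondrial ribosomal proteins. Cytosolic ribosomal proteins had a TE median of 0.14, above all random lists, with 65 of 75 above 0, Rpl32 at 0.57, and Rplp1 at -0.16 and Rpsa at -0.11 at the other end. The respiratory chain had a median of 0.07 (percentile 99.98), with Uqcr10 of complex III at 0.52 and Ndufc2 of complex I at 0.45. Its lowest members were Ndufa3 at -0.32 and Atp5d at -0.19. Mitochondrial ribosomal proteins had a median of 0.07 (percentile 99.7), with Mrps23 at 0.49 and Mrpl10 at -0.52. These last 2 medians were inside the range of random lists matched on coding length, at percentiles 65.4 and 70.5. Proteasome and chaperonin subunits had a median of 0.10 (99.8), with Psmd10 at 0.29 and Psmc1 at 0.23, and with Psmb10 at -0.12 and Psmb2 at -0.11 lowest. Translation factors had a median of 0.08 (99.7), with Eif1a at 0.78 and Eif3j at 0.42. At the low end of the translation factor list were Eif2c1 (Ago1) at -0.47 and Eif2c2 (Ago2) at -0.38, which are Argonaute proteins of RNA silencing and not initiation factors. Glycolytic enzymes had a TE median of 0.13 (percentile 98.7), with Hk1 at 0.36, Pfkm at 0.24 and Pgk1 at 0.19, and Pgam1 at -0.12. The interferon list stood at 0.17 (98.0), with Bst2, a membrane tether of viruses, at 0.52, but at 0.04 and inside the range with the floor 4 times higher.

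Pluripotency genes had lower TE, with a median of -0.13 (percentile 0.01) and 18 of 25 below 0. Their medians in RNA (0.07) and RPF (-0.04) were inside the random range. The DNA demethylase Tet1 stood at -0.47 (-0.57 to -0.37) and the transcription factor Sall4 at -0.36 (-0.45 to -0.27), while Gdf3 stood at 0.20 and Lin28a at 0.09. Among the secretory lists, TE medians were 0.09 for ER chaperones (percentile 98.7), 0.08 for ER translocation and N-glycosylation (98.5) and 0.09 for lysosomal and Golgi proteins (99.4). Erp44, an ER redox chaperone, stood at 0.32, Spcs1 of the signal peptidase at 0.36 and Sec61g of the translocon at 0.28, and both signal recognition particle receptor subunits were lower, Srprb at -0.32 and Srpr at -0.28. With random lists matched on coding length, the median of the translocation list was inside the range (percentile 90.1). Cholesterol genes stood at 0.10 (98.4), with Sc4mol at 0.23 and Srebf2, the transcription factor of the pathway, at -0.27, but were inside the range of unmatched lists.

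Inside the random range in TE were 11 of the 23 lists. Plasma membrane proteins had a median of -0.05, with the cadherin Celsr1 at -0.62 and Tgfbr1 at 0.40. Secreted and matrix proteins stood at -0.01 (mean 0.02), with Fbn1 at 0.56 and Col5a1 at -0.42, and solute carriers at -0.01, with the metal transporter Slc11a2 at 0.53 and Slc39a1 at -0.50. Numbered transmembrane proteins stood at 0.02 (-0.00 with the authors' totals), with Als2cr4 (Tmem237) at 0.55, Slc25 carriers at 0.06, with Slc25a36 at -0.44, and zinc finger proteins at -0.04, with Zfp462 at -0.56. p53 targets stood at -0.13, with Zmat3 at -0.39 and Bax at 0.35, ATF4 and unfolded protein targets at 0.04, with Mthfd2 at 0.30 and Slc7a5 at -0.32, and cell cycle genes at 0.03, with Mki67 at -0.60. Histones stood at 0.02, with Hist1h4h at 0.48 and Hist1h3c at -0.56, and trophoblast markers at -0.05 (mean 0.03). TE of Vim was 0.06, of Cubn -0.07, of Nes -0.19 and of Pax6 -0.01.

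**Figure D2:**
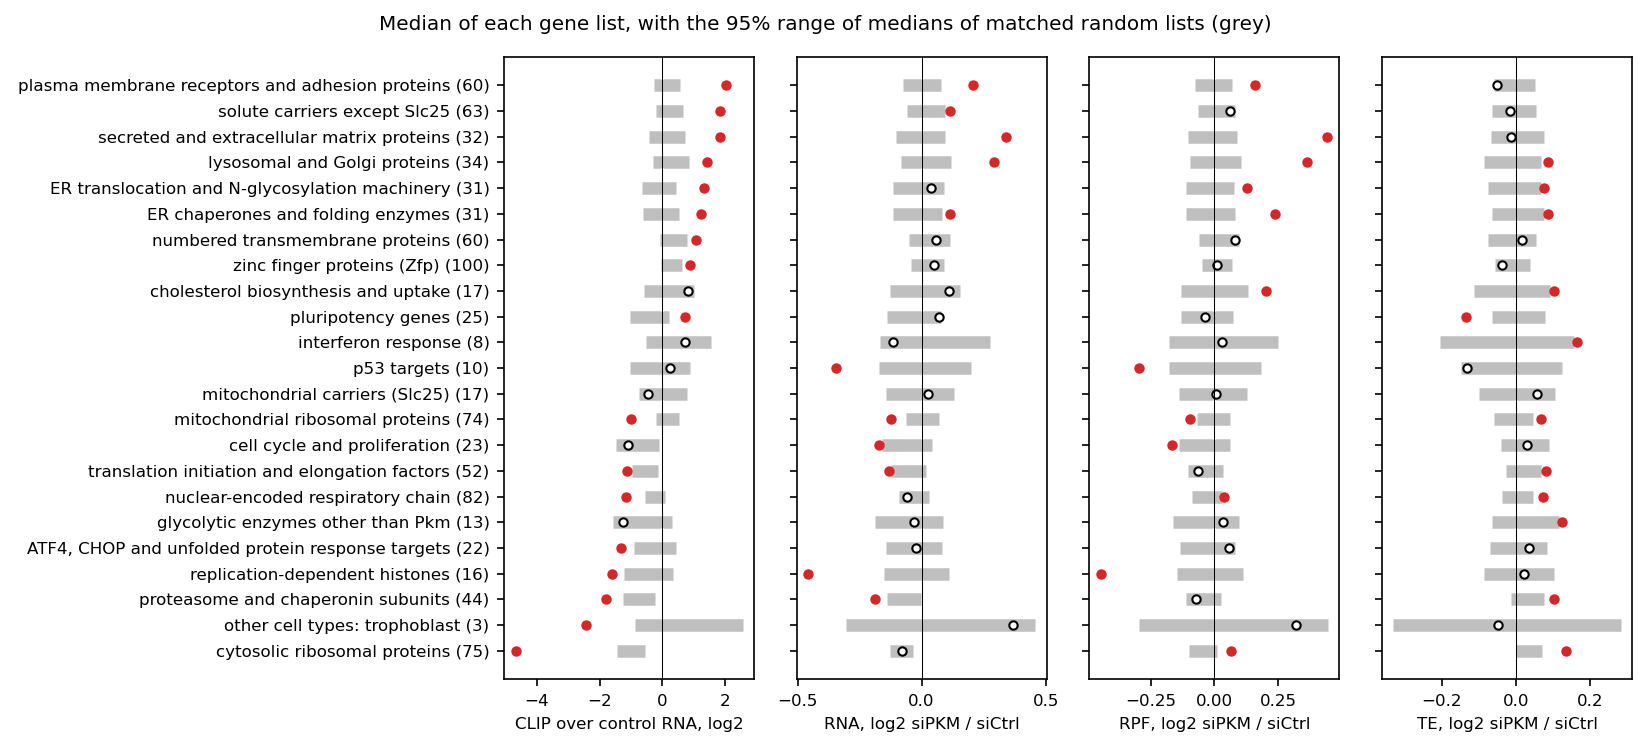
Median of each gene list (number of genes in brackets) in CLIP over control RNA and in the RNA, RPF and TE ratios of siPKM over siCtrl, all in log2; grey bars span the central 95% of medians of 10000 matched random lists, and red points lie outside them. ER and secretory lists lie on the right in CLIP over RNA, up to 2.04, and cytosolic ribosomal proteins on the far left, at -4.68. That low value is uncertain, since these genes have near-identical copies or pseudogenes. With the authors' totals the RNA medians of glycolytic enzymes and ATF4 targets and the TE median of numbered transmembrane proteins change sign.

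The CLIP libraries asked which RNAs tagged PKM2 contacts. The glucose transporter Slc2a3 had the most stops, at 4314 ± 174 CPM (stops scaled to the library's sum; SD, n = 2), followed by Tet1 at 3869 ± 164, the fatty acid desaturase Scd2 at 3645 ± 105 and Fn1 at 3490 ± 190. Nufip2 (3018 ± 60.0), Nucks1 (3007 ± 208), the splicing protein Srrm2 (3005 ± 570), the cytoskeletal linker Macf1 (2935 ± 147) and the heterochromatin protein Cbx5 (2700 ± 155) came next. ER chaperones were also among the first 20, with Canx at 2908 CPM, Hspa5 at 2644 ± 44.7, Hsp90b1 at 2251 ± 113 and Calr at 2038 CPM. The remaining ones were Igf2bp1 (2237), Pabpc1 (2231), Actb (2194), Flna (2173), a second glucose transporter, Slc2a1 (2039), Ncl (1956) and Nsd1 (1854). The Pkm message itself had 377 ± 13.3 CPM, with a log2 CLIP over control RNA of -3.56. Relative to RNA the highest were Myadm at 5.50 ± 0.10, ORF19 (Washc1) at 5.39 ± 0.14, the mitochondrial leucyl-tRNA synthetase Lars2 at 4.85 ± 0.28, Ankrd52 at 4.84 ± 0.02, the nuclear pore protein Pom121 at 4.57 ± 0.03 and Leng8 at 4.45 ± 0.14. Next were the histone methyltransferase Mll2 (Kmt2d) at 4.35, Grik3 at 4.30 ± 0.13, the transcription factor Zfhx3 at 4.27 ± 0.13 and AU018091, a cationic amino acid transporter by its description, at 4.26 ± 0.01.

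Messages of the secretory pathway were high in CLIP over RNA. The median was 2.04 for plasma membrane proteins, with all 60 above 0, 1.85 for solute carriers (62 of 63), 1.84 for secreted and matrix proteins, with Hspg2 at 4.22 and Fn1 at 3.32, 1.43 for lysosomal and Golgi proteins (34 of 34), 1.32 for ER translocation and N-glycosylation, 1.25 for ER chaperones (31 of 31), with Calr at 1.93 and Hspa5 at 1.78, and 1.07 for numbered transmembrane proteins. The median of numbered transmembrane proteins was at percentile 99.98 and those of the other 6 lists were above all 10000 random lists. Above 0 were 30 of the 32 secreted and matrix proteins, 28 of the 31 translocation members and 45 of the 60 numbered transmembrane proteins. Sec61g, 1 of the 3 translocation members below 0, lay far below it, at -3.75 (7 stops in each replicate). Zinc finger proteins stood at 0.89 (percentile 99.99) and pluripotency genes at 0.72 (percentile 99.9, but 97.2 and inside the range matched on coding length), with Tet1 at 3.21. Cytosolic ribosomal proteins were lowest at -4.68, with 0 of 75 above 0, followed by proteasome and chaperonin subunits at -1.79, histones at -1.61 (0.18), ATF4 targets at -1.32 (0.06), the respiratory chain at -1.16, translation factors at -1.12 (0.58) and mitochondrial ribosomal proteins at -0.99. Those given without a percentile were below all random lists. The treatment of stops with several matches was not given. Medians of lists with near-identical copies or pseudogenes, such as ribosomal proteins and histones, therefore do not show a lack of contact. The trophoblast median of -2.44 (percentile 0.01) rested on 3 genes, of which Krt18 had 0 and 2 stops and Krt8 had 1 and 2, while Tcfap2c stood at 0.26. It was -1.70 without replicate 1, -2.97 without replicate 2 and -0.48 with a pseudocount 10 times larger. Inside the range were glycolytic enzymes at -1.26, with Pgk1 at -5.49 ± 0.22 (SD, n = 2), cell cycle genes at -1.10, Slc25 carriers at -0.45, p53 targets at 0.26, interferon genes at 0.71 and cholesterol genes at 0.83. Pgam1 had 22 and 2 stops and stood at -4.44 in replicate 1 and -7.59 in replicate 2. Vim stood at -1.41 ± 0.13, and the other single markers rested on few stops, with Cubn at -0.31 (4 and 6 stops), Nes at -2.31 (8 and 4) and Pax6 at -2.39 (1 and 3). Nes ranged from -1.93 in replicate 1 to -2.83 in replicate 2 and Pax6 from -3.14 to -1.90. The gene mt-Nd4 had 0 stops in both replicates.

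The CLIP replicates had a Pearson correlation of 0.954 (log2) and a Spearman correlation of 0.962 across genes, and a chi-square of 1.98 per degree of freedom over 6147 genes, so they differed by more than sampling noise. CLIP level and control RNA level had a Pearson correlation of 0.490. A CLIP library from cells without the tag was not analysed here, so these values do not separate binding by PKM2 from background.

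Messages with high CLIP over RNA had lower TE in siPKM. The 653 genes with the highest CLIP over RNA, of which 15.9% were in a secretory list (4.76% of all genes), had a TE median of -0.15 (95% interval over genes -0.18 to -0.13), against -0.03 to 0.01 for matched random sets, and 77.5% of them were below 0. Among them were Ankrd52 at -0.75, Zfhx3 at -0.57, Pom121 at -0.54 and Mll2 at -0.53, while AU018091 stood at -0.15 and ORF19 at 0.03. Their RNA was higher in siPKM, with a median of 0.25 (random 0.01 to 0.06), and their footprints slightly so, at 0.06 (0.00 to 0.05). Those in a secretory list or described as precursors (149 genes) had a TE median of -0.04 with RPF at 0.22, and the other 504 a TE median of -0.20 with RPF at 0.03. The 653 genes with the highest CLIP level had a TE median of -0.06 (random 0.00 to 0.03), with 64.5% below 0, RNA of 0.07 and RPF of 0.00. Those with the most stops went both ways, with Macf1 at -0.72, Flna at -0.63 and Tet1 at -0.47, but Nufip2 at 0.13, Hspa5 at 0.11 and Slc2a3 at 0.10. CLIP over RNA and TE share the control RNA library. Their Spearman correlation across genes was -0.33, against -0.01 in simulations of counting error alone, and their covariance was -0.0983, against -0.0018, a difference of -0.0965; part of the excess may come from the shared control. With CLIP set against control footprints, the TE median of the 653 highest genes was -0.05, still outside the random range. Control footprints also enter TE, where low counts raise it, so part of the smaller size may come from that library.

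**Figure D3:**
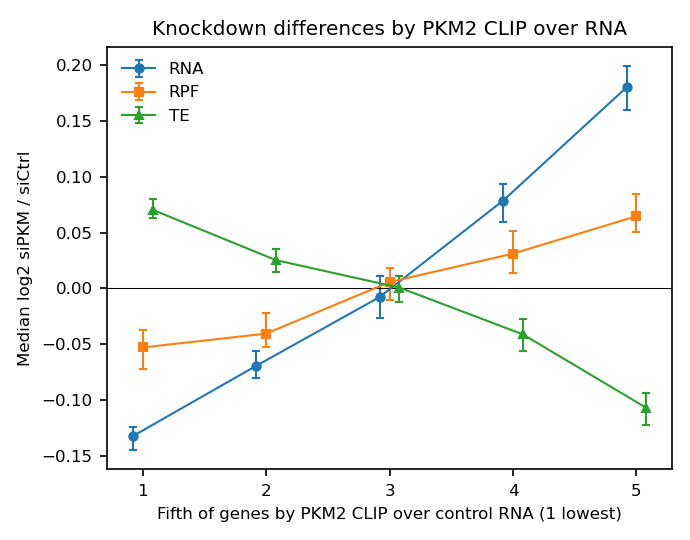
Median log2 ratio of siPKM over siCtrl in RNA, RPF and TE (vertical axis) in 5 equal groups of genes from the lowest to the highest CLIP over control RNA (horizontal axis); bars are 95% intervals of the median over genes. TE medians run from 0.07 to -0.11, RNA medians from -0.13 to 0.18 and RPF medians from -0.05 to 0.06.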

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

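These 5 results were picked out by a search of transcript parts that the comparisons above do not use, by a rule chosen after the data were seen. It took genes whose footprints in a part, relative to those in the CDS, were at least 1.5-fold higher in siPKM by at least 5 counting errors. The same limits in the other direction were met by more genes, 2 against 1 in the 5' UTR, 4 against 2 in the first 15 codons and 3 against 2 in the last 5, such as Tcea1 (5' UTR, -0.89), Lrpap1 (first 15 codons, -1.15) and Hist1h4h (last 5 codons, -0.84). Each rests on 1 library per group. Ucp2, a mitochondrial carrier, had 507 and 514 footprints in its 5' UTR (siCtrl, then siPKM) while its CDS had 621 and 365, a log2 difference of 0.79. Hist1h4i, a histone H4 gene, had 311 and 273 in the first 15 codons against 975 and 440 in the CDS, or 0.96. Tcea3, a transcription elongation factor, had 97 and 113 in the first 15 codons against 2122 and 1183, or 1.06. Dppa5a, a stem cell marker, had 319 and 419 in the last 5 codons against 28212 and 23330, or 0.67. Hist2h2bb, a histone H2B gene, had 383 and 358 in the last 5 codons against 12356 and 7550, or 0.61. In all 5 genes the CDS had fewer footprints in siPKM, which also was the shallower library.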

How the results depend on the processing

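The alternatives with random lists matched on coding length, with CLIP over control footprints, and with scaling of list medians were chosen after seeing the data. Of 204 planned recomputations of RNA, RPF and TE list medians, 197 stayed on their side of the random range, 4 moved inside, 3 moved outside and 0 outside the range changed sign. Of 207 added ones the numbers were 198, 6, 3 and 0. Among these, the 69 with TMM and the 69 with the authors' totals could not cross the range, since scaling shifts every gene alike. Only their signs could change. The 69 matched on coding length gave 60, 6, 3 and 0. For CLIP over RNA all 115 planned ones stayed, and of 46 added ones 41 stayed, 1 moved inside and 4 outside. At 2-fold, 21 genes were higher and 10 lower in RNA, 20 and 9 in RPF, 0 and 0 in TE. With the floor 4 times higher (5434 genes), TE counts were 5 and 35, because fewer genes of few reads were used. That floor moved the RPF median of numbered transmembrane proteins to 0.11 (percentile 97.7), that of cholesterol genes to 0.054 (79.8) and the TE median of interferon genes to 0.038 (70.3), and left too few trophoblast markers for a value. Unmatched random lists put numbered transmembrane proteins in RPF (0.081, percentile 98.6) and ribosomal proteins in RNA (-0.079, 1.18) outside, and the respiratory chain in RPF (0.037, 89.2) and cholesterol genes in TE (0.10) inside. Matched on coding length, inside were TE of ER translocation (0.077, 90.1), of mitochondrial ribosomal proteins (0.068, 70.5), of the respiratory chain (0.074, 65.4) and of cholesterol genes (0.10, 96.3), RNA of mitochondrial ribosomal proteins (-0.12, 3.58), RPF of the respiratory chain (0.037, 96.1) and CLIP over RNA of pluripotency genes (0.72, 97.2). Outside were numbered transmembrane proteins in RNA (0.057, 97.9) and RPF (0.081, 98.8), TE of p53 targets (-0.13, 1.27) and CLIP over RNA of glycolytic enzymes (-1.26, below all) and cell cycle genes (-1.10, below all). Over control footprints, CLIP of p53 targets was 1.83 (99.3) and of cholesterol genes 1.27 (98.9), now outside. Apart from the floor, the cause was not tested. Scaling by the authors' totals gave Pkm -1.67 in RNA and 240 higher and 62 lower genes in RNA; TMM counts stayed within 1.5 times. The TE median of the CLIP-high genes ranged from -0.15 to -0.16 without either replicate, was -0.19 in the highest twentieth and -0.11 in the fifth with the highest ratios. No floor was a void alternative, since the planned floor removed 0 genes. No paired analysis was possible because only the CLIP libraries carry replicate numbers. Depth limits CLIP values of genes with few stops, such as Krt8 (1 and 2 stops). The 22 and 2 stops of Pgam1 came from libraries of nearly equal depth (677701 and 670725 stops), and the cause of that difference was not tested.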

Other observations

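The TE comparison of genes high in CLIP over RNA was planned; the search of RNA in the 3' UTR, the wider sets, the tests with the coding length index, siPKM RNA or control footprints and the reading of the RPF median were chosen after the results were seen. In 8 genes RNA reads in the 3' UTR, relative to those in the CDS, were at least 1.5-fold higher in the siPKM library by at least 5 counting errors. The largest difference was that of Gmps, the GMP synthetase, at 1.22 (log2), where the CDS had 5277 and 3614 reads (siCtrl, then siPKM) and the 3' UTR 234 and 373. The RNA helicase Ddx49 stood at 0.91, the chaperone Hspa4 at 0.88, the RNA-binding protein Syncrip at 0.81, Arpp19, an inhibitor of a mitotic phosphatase, at 0.75, the RNA-binding protein Tial1 at 0.74, the mitochondrial fusion protein Opa1 at 0.72 and the phosphatase subunit Ppp2r5c at 0.63. The same limits were met in the other direction by 5 genes, among them Lcmt2 at -1.57, Dennd5b at -0.84, the ribosomal protein Rpl27 at -0.63 and the ketoglutarate dehydrogenase subunit Ogdh at -0.62. The median over 5618 genes was 0.00.

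A pair of wider sets was also described. Proteins whose deposited description said precursor, without mitochondrial ones (240 genes), had medians of 0.15 in RNA, 0.15 in RPF, 0.02 in TE (percentile 96.8) and 1.37 in CLIP over RNA. The 7 secretory lists together (311 genes) had medians of 0.13, 0.16, 0.03 (percentile 99.2) and 1.59, and 290 of the 311 were above 0 in CLIP over RNA.

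TE ratios were lower for longer coding sequences, with a Spearman correlation of -0.27 across genes between TE and the coding length index. A candidate explanation is that the RNA libraries recovered long and short messages differently. The RNA ratio followed the index (0.23, also 0.23 with an index from footprints), as this explanation requires. The footprint ratio hardly did (0.021, and 0.04 with the footprint index), which argues against a length bias of the RPF libraries acting alone. It cannot argue against an RPF bias that offset a real RNA difference by length, since the footprint ratio would then also be flat. Since each siRNA group had 1 RNA library, a real effect of the knockdown on RNA levels by length stays open and untested.

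Genes high in CLIP over RNA had a TE median of -0.15. Counting error of the control RNA library, which enters both measures, is argued against as the whole cause. The set chosen over siPKM RNA had a TE median of -0.14 (random -0.03 to 0.01). That choice cannot argue against uneven recovery of messages in the control RNA library, which enters TE with either reference. The set chosen over control footprints gave a smaller difference, as stated above, so the size depended on the reference. Coding length, as far as the read-based index measures it, is also argued against as the whole cause. Random sets matched on that index reached down to -0.039. Their RPF median of 0.062 was not below random sets (0.00 to 0.05), so their footprints were not fewer than those of matched genes. The 504 genes outside the secretory lists and precursors had RPF at 0.03 (random 0.00 to 0.06) and TE at -0.20. This cannot argue against fewer ribosomes per message, since level footprints beside higher RNA would also come from that. The lower TE went with higher RNA in the siPKM library, at a median of 0.25. Whether the higher RNA came from the loss of PKM or from any other difference between the siPKM and siCtrl cultures or libraries stays open. Each group had 1 siRNA treatment and 1 library of each kind.

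The 7 secretory lists together had a median CLIP over RNA of 1.59. Coding length, as far as the read-based index measures it, is argued against as the whole cause. Random sets matched on that index reached up to 0.30. The ribosome load of the messages is argued against too, since CLIP over control footprints had a median of 1.69 (random 0.23 to 0.63). No biological explanation was tested. Background of the crosslinking and purification stays open, since a CLIP library without the tag was not analysed here.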
